A study of Mus musculus with 4 samples.

How the data were processed

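Tissue was the dentate gyrus of C57BL6 mice about 9 weeks old from a line with FLAG-tagged Mbd1. Per the labels, sonicated chromatin was precipitated with anti-FLAG antibody for 2 ChIP libraries, 2 input libraries were made without antibody, libraries averaged 350 bp, and reads were single and 100 bp long. The labels do not say which animals each library came from. Reads were aligned with Bowtie 0.12.7 to mm9, per the submitters' processing notes. The peak caller, the rule for reads that align in several places, the handling of duplicate reads and the way in which libraries were combined are not given in the sources used here; the column names are like those of a MOSAiCS export.

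The deposited list holds 1 peak per line for the whole series. Its mean ChIP and mean input values are signal, as reads per bin averaged over the bins of a peak, per the file headers. The highest ChIP value of a peak is a whole-number count in 1 bin, per the file headers. The number of bins in a peak is not given. It was taken here as the number, nearest to a bin width of 200 bp, that made the sums of ChIP and input whole (tolerance 1e-06 reads); it lay within 1 of width over 200 in 81.2% of peaks. Summed counts, and the intervals and floors made from them, rest on this inference. The authors' scaled input was the input times a constant of 2.42 in all 37662 peaks with an input read. The deposited log2 value is the authors' mean over bins of the log2 ratio of ChIP to scaled input; log2 of the mean counts, with 1 added to each, differed from it by a median of -0.15. The deposited −log10 values were read, from their column names, as the mean p and the smallest p of a peak's bins. How this p was computed, and whether it is the p-value of a test, is not given in the sources used here. The smallest p was never above 0.05, the mean p reached 0.420, and the smallest p of 15 peaks was stored as infinite on this scale. The authors' quality flag, whose definition is not given, coincided without exception with a smallest p of at most 0.0001. Width, summit pile-up and scaled input were used as deposited.

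Because a peak enters the list only where ChIP exceeds scaled input (lowest log2 ratio 0.59), the ratios are selected to be high and carry no information on regions outside peaks. A mean of log2 ratios also depends on what was added to an input of 0. For named peaks the ratio was therefore computed again from summed counts with an exact binomial 95% interval, and where the input sum was 0 a bound was set with a floor of 3 counts. Library totals are not given, so the depth of each library is unknown; the constant of 2.42 is the only trace of the relative depth of ChIP and input. Reads are not independent molecules and can fall into more than 1 bin, so all intervals cover counting error only.

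Numbers, widths and covered bases were counted, medians were given with binomial 95% intervals, and shares with exact Clopper-Pearson 95% intervals. Chromosome density was taken over the span from first to last peak, since no chromosome lengths of this build were used, and set against 10000 random placements weighted by span, with a two-sided p and Benjamini-Hochberg adjustment over 20 chromosomes; Y was described apart. Ratios of densities have exact 95% intervals. Gaps between autosomal peaks were set against 100 random placements within chromosomes. The comparisons have no test across samples, because 1 list for 4 libraries has no replicates; the edgeR-type test foreseen for counts per library was not applicable.

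The stricter limit of 0.05 was set before the data were examined; it was applied to the mean p, a choice made after seeing that the smallest p met it in every peak. Peaks to be named were fixed before the data were examined: the 20 with the largest ratio on chromosomes 1 to 19 and X with ChIP at or above the median. Gene names, promoter shares, base composition, mappability and 22 gene lists were also foreseen and were not analysed here, as the only gene table used was for GRCm38.p6 and the peaks are on mm9. Input-poor peaks (input under 0.25 times the median) and input-rich peaks (over 4 times the median) were defined after seeing the data, as were 5 Mb windows; input-poor peaks within 1 Mb of each other were joined into blocks. Alternatives were stricter p, the higher-ChIP part of the list, merging of peaks under 1 kb apart, limits on input and covered bases, and, added after seeing the data, the quality flag, recomputed ratios, removal of X and Y or of input-poor peaks, 1 Mb windows, other input borders, and placement over autosomes alone.

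The calculations were tested on simulated data. In 25841 simulated peaks an X to autosome ratio made as 0.1 came back as 0.0959 and a chromosome 3 to 11 ratio of 2 as 2.20. In 200 simulated draws 95% of median intervals and 97.5% of ratio intervals held the true value. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.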

Results

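MBD1, a protein that binds methylated CpG, was mapped in the mouse dentate gyrus, the part of the hippocampus that holds granule neurons and adult neural stem cells. Chromatin from a mouse line with FLAG-tagged Mbd1 was precipitated with an anti-FLAG antibody (2 ChIP libraries) and set beside DNA that was not precipitated (2 input libraries). The data analysed here are 1 list of 37778 peaks for the 4 libraries together, with mean ChIP and input read counts per bin in each peak, the bins being about 200 bp wide as inferred from the values. The list holds no value per library, so no difference below has been set against replicate error, and every interval covers counting error or the spread over peaks only. Library totals are not given in the sources used here. All positions are on mm9.

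The first comparison, ChIP against input over the peaks, asks where in the genome anti-FLAG ChIP exceeded input and by how much. The 4 libraries include no anti-FLAG ChIP from untagged animals. Excess over input therefore cannot be assigned to tagged MBD1 apart from background of the antibody or chromatin. Enrichment over input was broad and mostly shallow. The 37778 peaks covered 148.2 Mb, with a median width of 3085 bp (interquartile range 1897 to 4989 bp). The median peak held 58.8 ChIP reads per bin (95% interval of the median 58.7 to 58.9) against 28.8 input reads after the authors' scaling of input to ChIP. The median deposited log2 ratio of ChIP to input was 1.20 (95% interval 1.20 to 1.21, interquartile range 0.96 to 1.51). It was under 1 in 10903 peaks (28.9%), above 2 in 2922 (7.73%), above 3 in 559 (1.48%) and above 5 in 178 (0.471%). The authors' quality flag was carried by 11654 peaks (30.8%, exact 95% interval 30.4 to 31.3%), which covered 51.3 Mb and had a median log2 ratio of 1.39, against 1.14 in the other 26124. A mean p of at most 0.05 over the bins kept 1198 peaks (3.17%, exact 95% interval 3.0 to 3.35%). The limit of 0.05 was set before the data were examined, and its use on the mean p was chosen after. How the p of a bin was computed is not given, so strict peaks are a narrower set and not peaks that passed a known test. These strict peaks covered 7.66 Mb, were wider (median 4258 bp) and had a median log2 ratio of 1.64. The list's name gives a false discovery rate of 0.20.

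The highest ratios stood mostly where input, their denominator, was nearly absent. A peak is called input-poor here when its mean input was under 0.25 times the list's median of 11.9 reads per bin, a border chosen after seeing the data. Such peaks numbered 413 (1.09%), and 116 of them had no input read. Their median ChIP count was 48.2 reads per bin and their median log2 ratio 4.45, against 58.9 reads and 1.20 in the 37354 peaks with ordinary input. Input-poor peaks made up 378 of the 559 peaks with a log2 ratio above 3 (67.6%, exact 95% interval 63.6 to 71.5%). All 413 had a ratio above 2 (lowest 2.60), where they were 14.1% of 2922 peaks. High ratios follow largely from the definition of the class, since no peak of the list had under 30 ChIP reads per bin. They made up 215 of the 1198 strict peaks (17.9%).

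**Figure D1:**
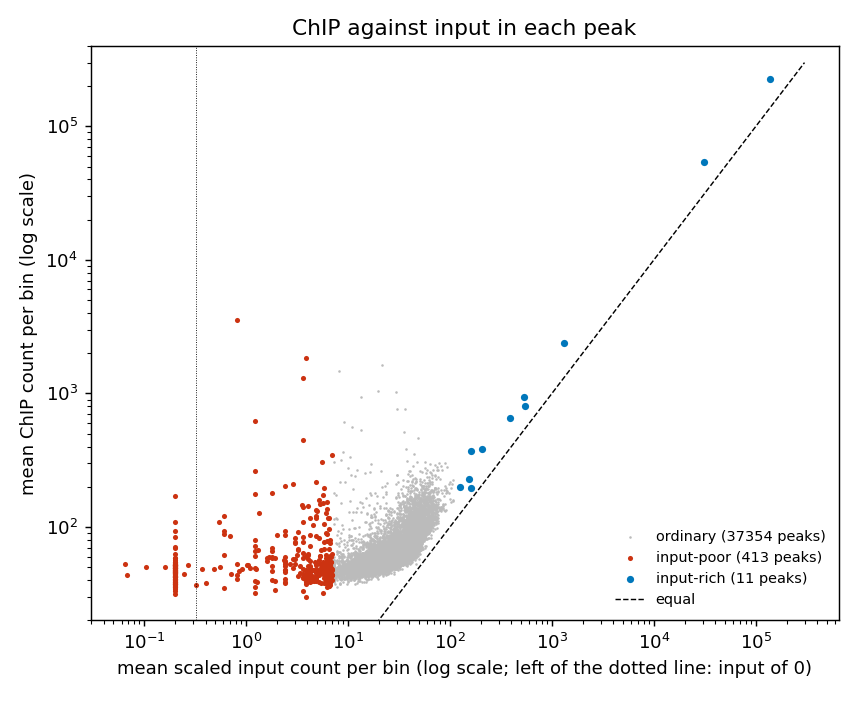
Mean ChIP count per bin (vertical, log scale) against mean scaled input count per bin (horizontal, log scale) for each of the 37778 peaks, with peaks that had no input read drawn left of the dotted line. The 413 input-poor peaks (red) lie to the left at a median of 48.2 ChIP reads per bin, lower than the 58.9 of ordinary peaks (grey), and the 11 input-rich peaks (blue) lie along the upper part of the dashed line of equal counts.

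The 20 peaks with the largest deposited log2 ratio, among those on chromosomes 1 to 19 and X with a ChIP count at or above the median, had ratios from 5.90 to 10.64. All 20 were input-poor, 7 of them without an input read; 8 lay between 119 and 124 Mb on chromosome X, 4 on chromosome 1, and 1 each on chromosomes 2, 4, 6, 8, 11, 13, 14 and 17. The highest, from 24618128 to 24623241 on chromosome 1 (5114 bp), had 3573 ChIP reads per bin, 9 input counts in all and a deposited log2 ratio of 10.64. Its summed ChIP count was 4431 times the scaled input (95% counting interval 2334 to 9690). This fold of summed counts is a different measure from the deposited mean over bins of log2 ratios, and the folds given below are of summed counts. Whether the sequence of this peak occurs elsewhere in the genome was not analysed here. The interval does not cover reads placed there from another copy, so the peak cannot be called the strongest MBD1 site. The next, from 120324953 to 120325599 on chromosome X, had 623.5 ChIP reads per bin over 2 input counts, a 515-fold ratio with an interval of 143 to 4258. From 69193354 to 69193965 on chromosome 2, 446.8 ChIP reads per bin stood over 6 input counts, 123-fold (56.4 to 336). From 85288502 to 85297304 on chromosome 1, a wider peak of 8803 bp had 109.8 ChIP reads per bin over 10 input counts, 204-fold (111 to 426). Peaks without an input read give only a lower bound, set against a floor of 3 input counts over the peak. It was at least 70.1-fold from 23235746 to 23236056 on chromosome 17 and at least 51.5-fold from 46536341 to 46536897 on chromosome 11. A read can be counted in more than 1 bin, so these intervals and floors are narrower than those of independent reads.

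Strong enrichment also occurred where input was ordinary. The autosomal peaks named here were chosen after their values were seen. From 36621179 to 36622169 on chromosome 17, ChIP reached 1639 reads per bin over 8.83 of input, 76.7-fold (58.6 to 102), and from 22443813 to 22447599 on chromosome 2 it reached 1039 over 8.05, 53.3-fold (45.5 to 62.9). From 7319892 to 7323599 on chromosome 18 the ratio was 42.0-fold (32.3 to 55.5), with an input of 3 reads per bin that lay just above the input-poor border of 2.98, and from 79648000 to 79651399 on chromosome 4, with 12.5 input reads per bin, 25.5-fold (22.2 to 29.3). A wide region of 40560 bp, from 25416057 to 25456616 on chromosome 3, held 252.9 ChIP reads per bin on average, 17.1-fold (16.1 to 18.1). A stretch of chromosome 17 between 59 and 62 Mb held 155 peaks with a median width of 6200 bp, which covered 49.5% of it and included 6 of the 20 widest peaks of the list. Their median log2 ratio was 1.10, below the 1.20 of the whole list. Strict peaks were nevertheless frequent among them, at 34 of 155 (21.9%) against 3.0% of autosomal peaks. On the rest of chromosome 17 without input-poor peaks the share was 5.58%. This stretch was densely covered by wide peaks, more often strict, but by its median ratio not strongly enriched.

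The second comparison sets the density of peaks on each chromosome against random placement over chromosomes 1 to 19 and X. Autosomes carried 37637 peaks, 15.6 per Mb of the span from first to last peak. Chromosome 3 was the densest (3241 peaks, 20.7 per Mb), followed by chromosomes 16 (18.4), 1 (18.2) and 15 (18.1). Chromosome 11 was the sparsest autosome (1081 peaks, 9.10 per Mb, 0.619 times the number placed there at random), below chromosomes 19 and 7 (both 11.5) and 9 (12.1), so that chromosome 3 had 2.28 times the density of chromosome 11. In 10000 random placements 11 autosomes lay above the 95% range and 6 below it; chromosomes 12 and 13 lay inside it (Benjamini-Hochberg adjusted p = 0.228 and 0.224 over 20 chromosomes). For chromosomes 1, 3, 11, 15, 16 and X the p was 0.0002, the smallest that the placements can give (adjusted p = 0.0003). These p-values treat peaks as independent and describe this list, not a difference between animals. The contrast between chromosomes 3 and 11 was absent among strict peaks (ratio 1.01). Placement over the autosomes alone, added after seeing the data, put chromosomes 8 and 14 inside the range and 13 below it. Strict peaks were densest on chromosome 17, at 1.57 per Mb against 0.469 on all autosomes, followed by chromosome 5 at 0.934. Settings added after seeing the data gave chromosome 17 a density of 1.20 without input-poor peaks, against 0.846 on chromosome 5, then 1.24 without 59 to 62 Mb, and 0.863 without either.

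**Figure D2:**
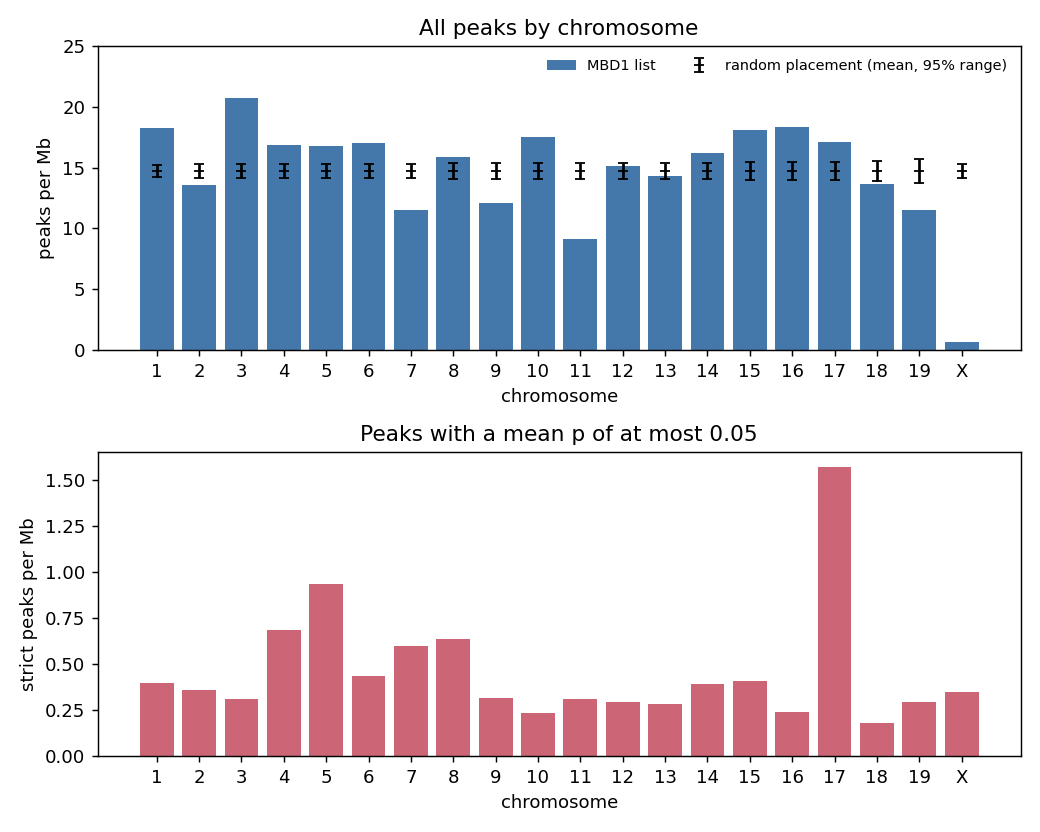
Peaks per Mb (top) and strict peaks per Mb (bottom) for chromosomes 1 to 19 and X, with the mean and 95% range of 10000 random placements as black bars in the top panel. Chromosome 3 (20.7 per Mb) and chromosome 11 (9.10) are the extremes among autosomes, chromosome X holds 0.693, and chromosome 17 leads among strict peaks (1.57).

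Chromosome X was almost free of peaks. It held 112, or 0.693 per Mb, which is 0.0443 times the autosomal density (95% counting interval 0.0365 to 0.0534). The peaks it had were narrow (median 984.5 bp). Their medians were 84.1 ChIP and 2.93 input reads per bin, against 58.8 and 11.9 on the autosomes. The median log2 ratio was 3.98 against 1.20, a contrast to which the low input contributes. No peak of the list had a mean ChIP under 30 reads per bin, and the 5th percentile of autosomal peaks was 49.6. X sites with fewer reads, as lower coverage of X would give, would therefore mostly not appear in it. Read coverage of X outside peaks was not analysed here. The authors' quality flag was carried by 88.4% of X peaks against 30.6% of autosomal peaks, and 56 of 112 were strict (50%, exact 95% interval 40.4 to 59.6%) against 3.0%. Among strict peaks the X to autosome ratio was therefore 0.739 (0.555 to 0.967). Of the 112 X peaks, 60 lay between 119 and 124 Mb, with a median of 115.8 ChIP reads per bin over 2.2 of input, and 45 of the 56 strict X peaks were there. Another 10 lay beyond 165 Mb, at 8.50 per Mb against 0.636 on the rest of X. These distal peaks looked autosomal, with a median of 57.2 ChIP reads, 10.3 input reads and a log2 ratio of 1.24. The borders, chosen after seeing the data, are whole Mb around the blocks of 5 or more input-poor X peaks and before the last run of X peaks less than 1 Mb apart.

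**Figure D3:**
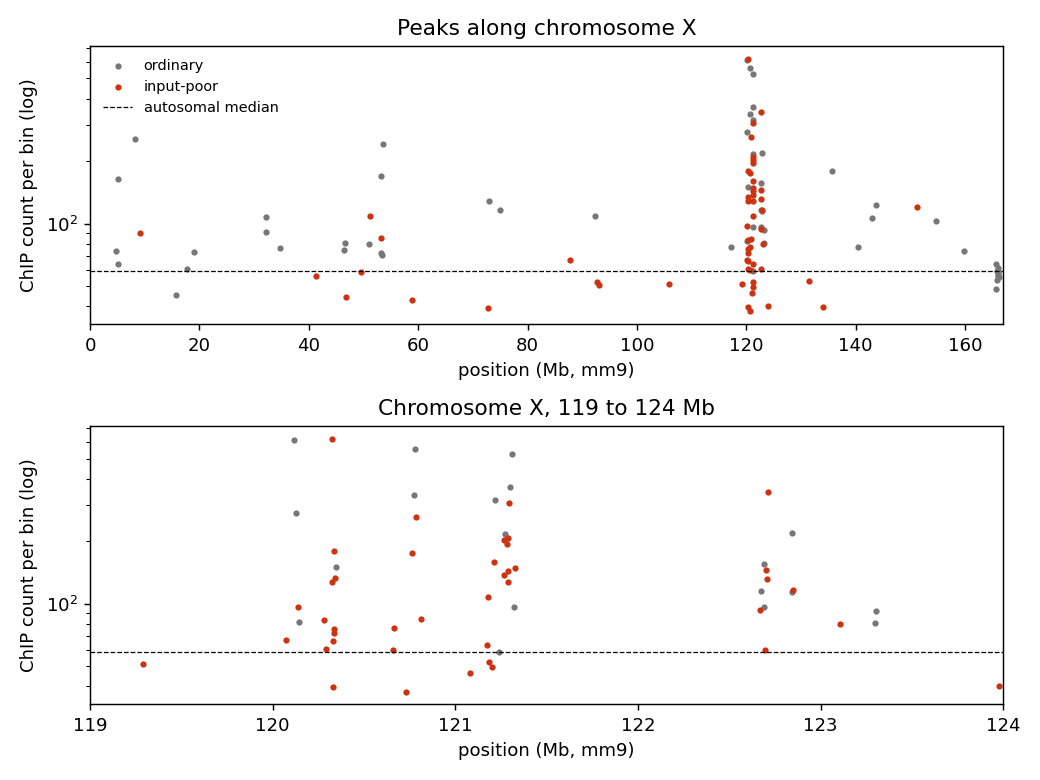
Each X peak at its mm9 position in Mb (horizontal) and its mean ChIP count per bin (vertical, log scale), for the whole chromosome (top) and for 119 to 124 Mb (bottom); input-poor peaks are red, ordinary ones grey, and the dashed line is the autosomal median. Of 112 peaks, 60 stand between 119 and 124 Mb and 10 beyond 165 Mb.

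Along the autosomes peaks were unevenly spread. In 465 windows of 5 Mb, a size chosen after seeing the data, the median was 58 peaks and the range 0 to 288. The 47 densest windows, with 159 peaks or more, held 25% of autosomal peaks, and the 49 sparsest, with 19 or fewer, 1.91%. The densest were 55 to 60 Mb on chromosome 5 (288 peaks, covering 33.3% of the window) and 85 to 90 Mb on chromosome 2 (284 peaks, 31.1%). The window from 40 to 45 Mb on chromosome 7 held none. Peaks in the densest windows were wider and weaker in ChIP than those in the sparsest (median 3553 against 1589 bp, 56.3 against 74.9 reads per bin), and their input was lower (10.5 against 16.6), so their log2 ratio was higher (1.33 against 1.05). The authors' quality flag went the other way, at 28.6% of peaks in the densest windows against 51.9% in the sparsest. In 1 Mb windows the flagged share was almost unrelated to peak number (Spearman's rho -0.02). Across the 457 windows with 10 or more peaks, Spearman's rho of peak number with median ChIP was -0.88 (Pearson's r -0.52), with median input -0.83 (r -0.69) and with median log2 ratio 0.56 (r 0.28). Within each of the 19 autosomes the 3 relations kept their sign. Windows are not independent replicates, and no p is given.

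**Figure D4:**
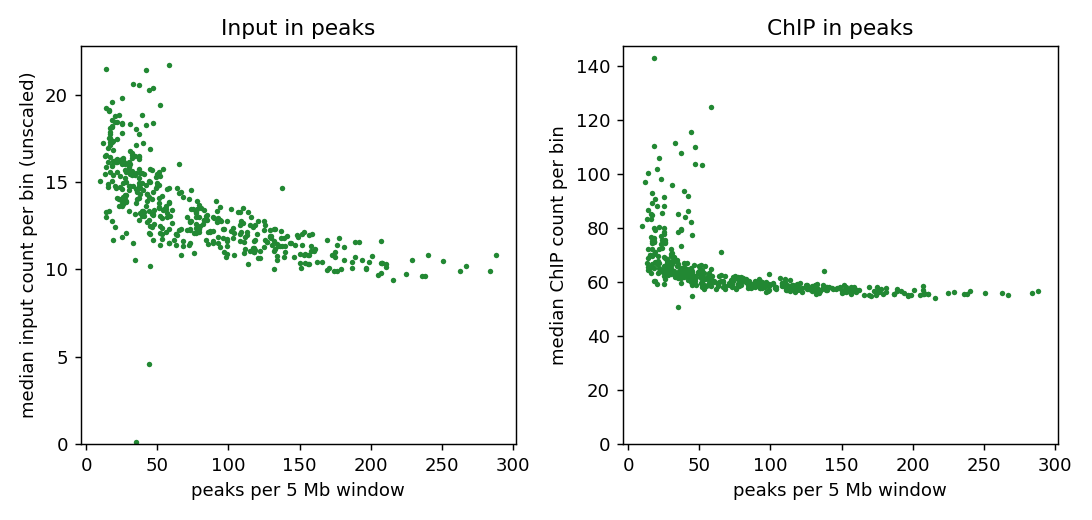
Median input count per bin without scaling (left) and median ChIP count per bin (right) against the number of peaks per 5 Mb window, 1 point per autosomal window with 10 or more peaks. Both fall from sparse to dense windows (rho -0.83 and -0.88).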

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

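Chosen only after seeing the data were the use of the mean p for the stricter limit, the quality flag, recomputed ratios, removal of X and Y or of input-poor peaks, other input borders, 1 Mb windows, chromosome 17 without its dense stretch and placement over autosomes alone. The stricter p left 1198 peaks on 7.66 Mb with a median log2 ratio of 1.64, an X to autosome ratio of 0.739 and a chromosome 3 to 11 ratio of 1.01. The higher-ChIP part of the list had 18889 peaks on 58.9 Mb and a log2 ratio of 1.06, and the quality flag 11654 peaks on 51.3 Mb, 1.39, an X ratio of 0.128 and a 3 to 11 ratio of 1.65. Fewer peaks follow from these limits by construction. The p compares ChIP with input and the flag coincided with a limit on it, so higher log2 ratios under both can follow from the selection. A lower ratio under a limit on input, its denominator, can do so too. The cause of the other shifts was not tested. The median log2 ratio was 0.96 with input at or above its median and 1.03 recomputed from mean counts. By covered bases the X ratio was 0.0242 and the 3 to 11 ratio 2.44; without input-poor peaks the X ratio was 0.0224. The X ratio stayed below 1 in the 4 settings in which it was computed. Merging peaks under 1 kb apart gave 36879 peaks on 148.7 Mb, and leaving out X and Y or peaks without input kept the median ratio at 1.20. Input-poor peaks numbered 1778 and 206 with borders at 0.5 times and 1/8 of the median. Placement over autosomes alone left 9 autosomes above and 7 below the random range, in place of 11 and 6. In 1 Mb windows rho of peak number with the share carrying the quality flag was -0.02, against -0.49. No paired analysis was possible because the list holds no values per library; leaving out each replicate was not possible for the same reason. The mappability, base composition, promoter and gene list alternatives were not run.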

Other observations

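All tests in this part were chosen only after the result, or a related value of the same list, was seen. Peaks stood closer together than chance. The median gap between autosomal peaks was 19277 bp, against a mean of 40509 bp in 100 random placements within chromosomes (lowest to highest 39841 to 40980). Gaps under 10 kb made up 32%, against 15.8% (lowest to highest 15.4 to 16.6%). Chromosome Y had 29 peaks, none beyond position 2902795, with medians of 80.4 ChIP and 4.63 input reads per bin. How far the assembled sequence of Y reaches in this build was not analysed here, so nothing can be read from that end point. The widest peak of the list was there, from 2847216 to 2902795 (55580 bp), with 1481 ChIP reads per bin over 3.39 of input and a log2 ratio of 7.55. A neighbour from 2779380 to 2797625 had 1827 over 1.60.

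Input-rich peaks were rare, with 11 in the list. The highest ChIP count of all, 227445 reads per bin from 98502143 to 98505600 on chromosome 2, stood over an input of 56480 and was 1.66 times the scaled input; whether its sequence is repeated in the genome was not analysed here. From 103598811 to 103599792 on chromosome 6, 53794 ChIP reads per bin stood over 12924 of input, 1.72 times after scaling.

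Some input-poor peaks stood together: joined within 1 Mb they formed 193 blocks, of which 141 were a single peak and 14 held 5 or more, with 172 of the 413 peaks. More ChIP reads than in other peaks were not excluded: on the autosomes the median was 47.3 reads per bin (46.2 to 48.2) against 58.8 in other peaks, but ChIP and input rose together across ordinary autosomal peaks (rho 0.69), so a lower ChIP count at low input can follow from the selection of peaks, and 2 of the 11 autosomal blocks of 5 or more had a median ChIP above 58.8. A candidate explanation is sequence read in ChIP but missing from the input libraries: 8 of these 11 blocks had a median input of 0, in peaks that covered 11.9 to 173 kb per block, and from 5616237 to 5778412 on chromosome 7 none of the 17 peaks had an input read. A mapping filter applied to input alone and a copy number that differed between animals cannot be told apart without read alignments. In such peaks between 119 and 124 Mb on X the median ChIP count was 97 (72.2 to 137), above autosomal peaks, but their input was also low, so more ChIP reads and missing input cannot be told apart there; no biological explanation was tested.

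The few peaks on X were weighed next. Outside 119 to 124 Mb the X to autosome ratio was 0.150 among strict peaks (0.0745 to 0.269) and 0.0212 among all peaks (0.0159 to 0.0279). The first ratio rests on 11 strict peaks among 52 on X. The strict limit sets ChIP against input, and input was low in X peaks. A higher ratio among strict peaks can follow from that, so a uniform loss over peaks of all strengths was not excluded. The fullest 1 Mb of X outside that region held 10 peaks. That number was reached in 1 of 3800 draws in which an autosome was thinned at random to the density of X. Over the draws the median was 4 (95% range 3 to 6). The distal X peaks described above lie within 1 Mb and by themselves make up the 10. The test thus describes a cluster already seen, so it cannot decide whether the loss was even along the chromosome. Halved coverage of a single X copy may contribute: 42 X peaks had 0.224 times the input of autosomal peaks of equal ChIP (0.167 to 0.280), lower than the 0.35 to 0.65 it would give, but peaks are selected for low input, coverage outside peaks was not analysed here, and it cannot be told apart from other causes. Peaks on Y had a median of 4.63 input reads per bin, so reads that align to Y were present in the input. The sex of the animals was not analysed further and no biological explanation was tested.

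Dense windows were tested at equal counts. Among 7597 autosomal peaks between the 40th and 60th percentile of input, ChIP and window density had a rho of -0.169 (-0.296 to -0.054 over 19 autosomes, above 0 in 0 of them); peaks just past the limit on ChIP over input can lower the ChIP count of a window as they add to its number, so more ChIP reads are not excluded. Among 7322 peaks between the 40th and 60th percentile of ChIP, input and density had a rho of -0.197 (-0.293 to -0.087, below 0 in 19 of 19). Dense windows may therefore owe part of their peaks to lower input coverage, a hypothesis from the same list in which peaks had to pass a limit that ties ChIP to input. Base composition and mappability stay open, and no biological explanation was tested.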
